A study of Homo sapiens with 16 samples.

How the data were processed

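The study compared 2 groups of 8 arrays, HDMEC transduced with MEK5/CA and the same lines transduced with LacZ. The cells were grown to confluence, per the labels' protocols, and total RNA was extracted on columns with a DNase step and labelled with biotin. Sample groups and replicate numbers were taken from the sample titles. The series design text describes the transduced lines as pairs from a common primary isolate, and the replicate number carries that pairing. The names of the lines give 3 couples that share a number, and whether the members of a couple share a donor is not given in the sources used here.

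The deposited values were linear intensity, 1 signal per probe set and array, in a table of 30573 probe sets for 16 arrays. The submitters' processing notes name MAS5, the Affymetrix signal algorithm, with no version or settings. The scaling target and the rule by which probe sets were kept in the table are not given in the sources used here. The median signal of an array lay between 478 and 508, the 75th percentile between 1661 and 1729 and the 2nd percentile between 12.8 and 18.6, so the arrays had been brought to a similar level before deposit. No 2 arrays were identical. For arrays the number of replicates, here 8 per group, sets the precision. The deposited signal is limited at the low end by background.

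Probe sets were named through the platform's annotation, a table dated 2016, and symbols were checked by Entrez ID against RefSeq genes of assembly GRCh38.p14, used for names only. Of the probe sets, 24841 had 1 symbol, 1169 had several and 4563 had none. Of the first, 24826 matched the gene table and 0 symbols changed. Probe sets with several symbols, those with none and the 41 Affymetrix control probe sets were left out of the gene tests, as were 16 probe sets of Y-linked genes and XIST. The array values carry no genome build, so no coordinates are given.

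Signals were used as deposited, without rescaling, as log2(signal + 16). Probe sets with a mean log2 signal over all 16 arrays below the 40th percentile of the non-control probe sets were removed (a signal of 292 at the limit), which left 18319. Each gene was represented by the probe set with the highest mean log2 signal. This gave 13096 genes before and 9533 after the filter. Differences were estimated with limma 3.58.1 in R 4.3.3 (lmFit with the replicate number as a block, eBayes with a trend) over all 16 arrays and adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Fold changes are MEK5/CA over LacZ on the log2(signal + 16) scale. A value given as ± beside a log2 fold change is its standard error, and beside a signal the SD. Adjusted p-values of single genes are from this limma test. Single measures of the arrays were compared by an exact two-sided sign-flip permutation test over the 8 pairs.

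Before the data were examined, 21 gene lists were fixed for the pathway, the cell type and other cell types the cultures could hold. They were the ERK5 cascade, the Krüppel-like factors, flow-responsive vasoprotective genes, TNF and NF-kB responsive genes, TNF receptors and signalling, coagulation and fibrinolysis, vasoactive genes, angiogenesis, Notch and arterial genes, NRF2 targets, ERK1/2 and immediate early genes, cell cycle, cholesterol synthesis, interferon response, ATF4 and unfolded protein response, TGF-beta and matrix genes, and markers of endothelium, lymphatic endothelium, fibroblasts and mural cells, keratinocytes and epithelium, and leukocytes. Some genes belong to several lists. Each list was tested against the other genes with camera in limma at a preset correlation of 0.01, adjusted over the lists. It was tested again with a correlation estimated from the residuals. That second test could be stricter even for a list of low correlation. For the interferon list, with an estimate of -0.00385, the camera p went from 3.94e-06 to 0.00187.

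The genes named were set by a rule fixed at the same time. It took 9 genes always, the 12 with the largest increase and the 12 with the largest decrease among called genes that moved the same way in all 8 pairs, and up to 4 members of each list with the smallest adjusted p. It named 98 tested genes. A further 20 tested genes were named after their values were seen, as the text says at each. Genes below the filter are given by level, with the test without the filter beside it where it is named. Of the 118 genes, 56 had more than 1 probe set past the filter, none of these had probe sets called in opposite directions, and 1, PTGDS, had probe sets differing by over 1 on the log2 scale. Probe sets ending in _x_at or _s_at can bind transcripts of several genes.

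The pairing was checked on the deviations of the arrays from their group means. The correlation of the LacZ and MEK5/CA arrays of a pair was between 0.119 and 0.735, against a median of -0.104 for arrays of different pairs, and 4 of 8 LacZ arrays correlated best with their own partner. Deviations from a group mean push the correlation of different pairs below 0 where partners correlate above it, so that median is no independent baseline. The block was kept because the design text describes the pairs.

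The steps were tested on simulated data, 8 pairs with 9533 genes of which 200 were changed. At 1.25-fold 24 of 50 changed genes were recovered, at 1.5-fold 40 of 50, at 2-fold 48 of 50 and at 4-fold 50 of 50, and 8 of 170 calls were false. The Benjamini-Hochberg cut-off depends on the share of changed genes. In the real data 2437 of 9533 genes were called, so these recovery rates do not carry over to them. In the simulated data the 1 shifted list was called and 0 of 19 others. The simulated genes varied independently of each other. The list result therefore does not carry over to lists of correlated genes, such as cell cycle (estimated correlation 0.869 in the real data).

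The alternatives planned before the data were examined were the fit without the block, pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, quantile normalization, scaling to a common median, the mean of a gene's probe sets, leaving out probe sets ending in _x_at or _s_at, eBayes without trend, array quality weights, averaging lines that share a number to give 5 pairs, and leaving out each pair in turn. A further 2 were added after seeing the data, the log2 ratio of the beta-actin 3' to 5' control as a covariate in the paired fit and centring each array on its hybridization controls.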

Results

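Total RNA from human dermal microvascular endothelial cells (HDMEC), primary endothelial cells of the small vessels of the skin, was hybridised to 16 Affymetrix expression arrays. The cells had been transduced with MEK5/CA, known in the field as a constitutively active form of the kinase MEK5, or with LacZ, which encodes a bacterial enzyme and served as control. There were 8 arrays per group, and each MEK5/CA culture had a LacZ partner from the same primary isolate, giving 8 pairs. The table held 30573 probe sets, of which 24841 carried a single gene symbol. After the filter on low signal and the choice of 1 probe set per gene, 9533 genes were tested. The median signal of an array lay between 478 and 508, and the 75th percentile between 1661 and 1729. The number of arrays limits the precision of every value below.

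Some array measures differed between the groups. The mean log2 ratio of the 3' to the 5' beta-actin control probe set, which is larger in degraded RNA, was 1.16 ± 0.25 (SD, n = 8) in LacZ and 0.89 ± 0.12 in MEK5/CA, and was higher in MEK5/CA in 1 of 8 pairs (exact two-sided sign-flip p = 0.0234). For the GAPDH control the log2 ratio was 0.27 ± 0.15 in LacZ and 0.15 ± 0.07 in MEK5/CA (exact p = 0.0703). The hybridization controls are labelled transcripts added at a fixed amount just before hybridization, so they do not track the amount of RNA in the cells. Their log2 signal averaged 13.62 ± 0.27 in LacZ and 13.33 ± 0.17 in MEK5/CA (exact p = 0.0312). The 100 brightest probe sets took 10.9% ± 1.02 of the signal in LacZ and 9.72% ± 0.582 in MEK5/CA (exact p = 0.0312). The smallest p that 8 pairs allow in this test is 0.00781. These differences accompany all of the gene comparisons that follow.

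The first comparison concerned the transduced gene and the kinase cascade it belongs to. Transcripts of MAP2K5, which encodes MEK5, were 1.60-fold higher in MEK5/CA, at a signal of 1881 ± 298 (SD, n = 8) against 1182 ± 248 in LacZ (log2 fold change 0.68 ± 0.11 SE, limma adjusted p = 0.00117, higher in 8 of 8 pairs). MAPK7, which encodes ERK5, the kinase that MEK5 phosphorylates, was 1.90-fold higher (log2 0.93 ± 0.11). MEF2A, a transcription factor, rose by 0.87 ± 0.11 on the log2 scale, whereas the related factor MEF2C fell by 0.41. Of the 9 tested genes of the ERK5 cascade list, 5 rose, 3 fell and 1 did not pass the test, with the same counts when adjusted over the list alone. The list as a whole did not stand apart from the other genes (camera adjusted p = 0.312). The probe sets of MAP2K5 differed among themselves. The log2 fold change was 0.68 for the probe set ending in _s_at, 0.63 for that ending in _x_at and -0.04 for the remaining probe set, which was not called, so that MAP2K5 lost its call and changed sign when probe sets ending in _x_at and _s_at were left out. Which of these probe sets lie within the transduced sequence is not given in the sources used here. MEF2C no longer passed when arrays were centred on the hybridization controls (log2 -0.12, adjusted p = 0.425).

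MEK5/CA changed the signal of 2437 of the 9533 genes tested (25.6%) at an adjusted p below 0.05, 1184 of them higher and 1253 lower. Most changes were small. In 1760 of the called genes the change was under 1.5-fold, the median absolute log2 fold change of called genes was 0.40, and 186 genes were at least 2-fold higher against 56 at least 2-fold lower. The direction was the same in all 8 pairs for 1490 called genes, 801 higher and 689 lower. The counts moved with the handling of the pairs and of the array measures above. Without the pairing in the model 749 genes were higher and 662 lower, with the beta-actin ratio as a covariate 474 and 213, and with the lines whose labels share a number averaged, which leaves 5 pairs, 854 and 803. Centring each array on its hybridization controls shifted the median log2 fold change of all genes from -0.01 to 0.28 and gave 3359 higher and 187 lower genes, so that 94.7% of calls were increases against 48.6% in the values as deposited. All fold changes given here are relative to the deposited scale.

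IGFBP5, a binding protein of insulin-like growth factors, had a signal of 62.8 ± 41.6 in LacZ and 15551 ± 3597 in MEK5/CA (log2 fold change 7.82 ± 0.21, adjusted p = 8.62e-10). The secreted protease ADAMTS1 rose by 5.79 ± 0.38, the nuclease DNASE1L3 by 5.40 ± 0.14, the calcium-binding protein S100P by 4.54 ± 0.23 and thrombomodulin, THBD, by 4.42 ± 0.17. RNASE1, a ribonuclease secreted by endothelium, and SLC6A6, the taurine transporter, both rose by 4.09. They were followed by IGFBP6 and CCDC69 (both 3.96), MN1 (3.83), C19orf33 (3.67) and EMP3 (3.64). These 12 genes rose in 8 of 8 pairs, which was a condition for their selection. Some of these log2 fold changes are not exact, because LacZ signals lay at or under 18.6, the highest 2nd percentile of an array, in 4 arrays for ADAMTS1, 2 for IGFBP5 and 1 each for S100P, CCDC69 and EMP3. The single pairs ran from 3.92 to 7.19 for ADAMTS1 and from 6.86 to 8.99 for IGFBP5, and with pseudocounts of 64 and 1 the values were 4.81 and 6.54 for ADAMTS1 and 6.98 and 8.34 for IGFBP5. The values come from 1 probe set per gene. Other probe sets, below the filter, mostly gave less, with 2.27 to 4.75 in 5 for IGFBP5 and 4.68 for ADAMTS1. They gave 2.68 for DNASE1L3, 3.69 and 2.02 for SLC6A6 and, above the value used, 4.49 for CCDC69. With the beta-actin ratio as a covariate EMP3 was at 2.22 and IGFBP6 at 3.33, both still called. Because 16 was added to each signal before the logarithm, the fold changes of genes with a low LacZ signal are understated.

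The decreases were smaller in size. FST, which encodes the activin-binding protein follistatin, fell by 2.87 ± 0.33 on the log2 scale, from a signal of 9689 ± 5487 in LacZ to 1644 ± 1567 in MEK5/CA (SD, n = 8, adjusted p = 1.00e-04). RASSF2 fell by 2.28 ± 0.23. The membrane-bound carbonic anhydrase CA4 fell by 2.07 and the cytosolic CA2 by 1.67, and the homeobox gene HLX fell by 2.03. The other genes among the 12 with the greatest decreases were MRAP2 (-1.94), FREM3 (-1.93, with 1 MEK5/CA array at background), MTARC1 (-1.79), the protease inhibitor gene TFPI2 (-1.65), MFAP3L (-1.64), IGFBP2 (-1.52) and the adenylate kinase gene AK5 (-1.50). These 12 genes fell in 8 of 8 pairs, again a condition for their selection. With the beta-actin ratio as a covariate the calls of CA4 (log2 -1.23, adjusted p = 0.0922) and TFPI2 (-1.67, adjusted p = 0.112) were lost, and TFPI2 and MFAP3L were not called without the pairing.

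The series names KLF4 and shear stress, so the Krüppel-like transcription factors and a list of genes known to respond to laminar flow were examined next. KLF4 was 8.23-fold higher in MEK5/CA, with a signal of 18932 ± 3124 against 2627 ± 1495 in LacZ (SD, n = 8; log2 3.04 ± 0.21 SE, adjusted p = 2.32e-06, exact sign-flip p = 0.00781). KLF2 was 5.54-fold higher, at 16091 ± 2944 against 3343 ± 2011 (log2 2.47 ± 0.25, adjusted p = 4.5e-05). Both were higher in 8 of 8 pairs. KLF10, a factor induced by TGF-beta, rose by 1.22 ± 0.11 and KLF7 by 0.37 ± 0.07. Of the 11 tested members of the family, 9 rose, 1 fell and 1 did not pass, and the counts were the same when adjusted over the list alone. The tested member that fell was KLF15 (-0.89 ± 0.23), named after its values were seen. Below the filter KLF5, also named after its values were seen, fell in the test without the filter (-0.84 ± 0.14, adjusted p = 0.00124). KLF8 and KLF16, also below it, did not pass there. The family stood above the other genes (mean log2 0.75, camera adjusted p = 4.39e-05), but not with an estimated correlation between genes (adjusted p = 0.160). KLF2 and KLF4 have only probe sets ending in _s_at past the filter (another of KLF2, below it, gave 1.14), and the list without such probe sets had a mean of 0.09 (adjusted p = 0.0801). With the beta-actin ratio as a covariate KLF7 (adjusted p = 0.119) and KLF15 (log2 -0.38) were not called.

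**Figure D1:**
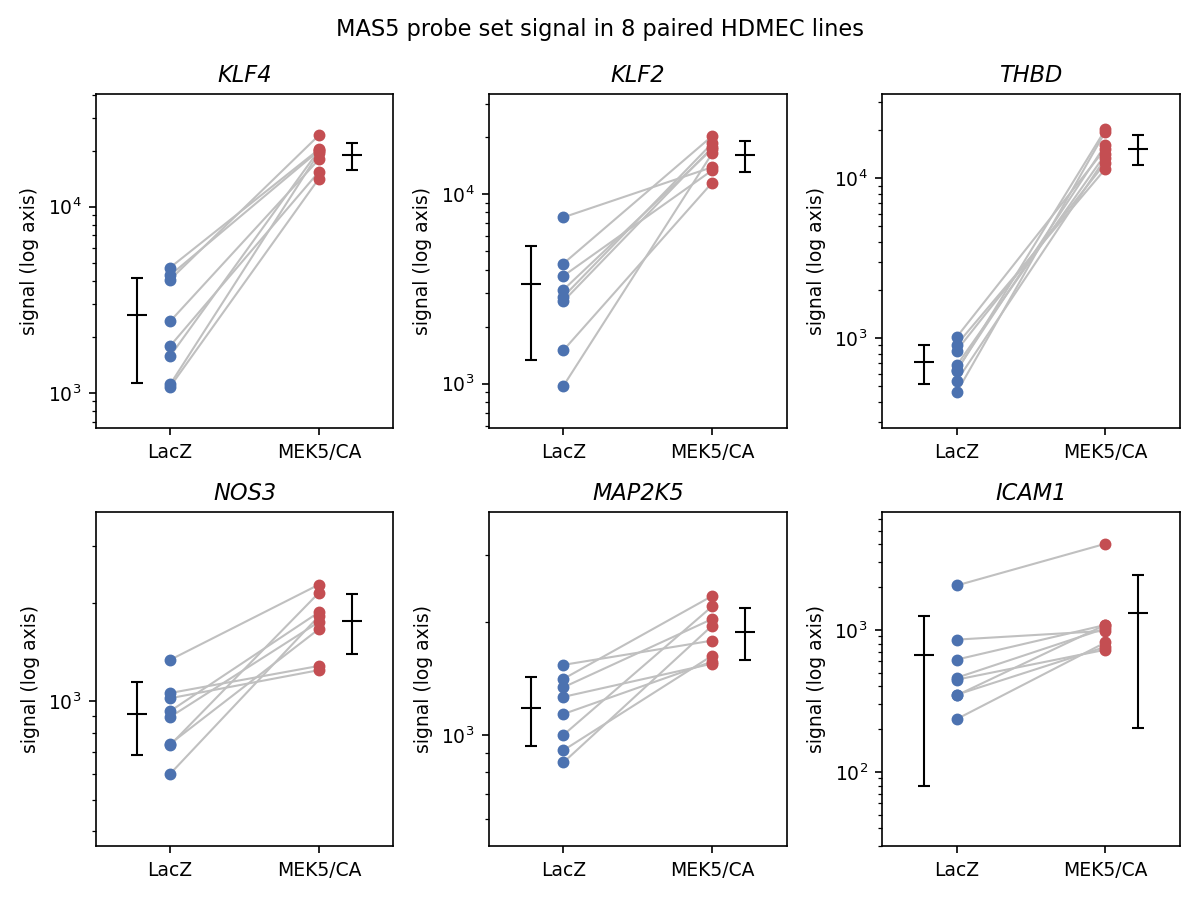
Signal of 6 genes on a log axis in LacZ (blue) and MEK5/CA (red) cultures, with a grey line joining the cultures of each of the 8 pairs. The black marks beside the points give the mean and SD of each group. All 6 genes were higher in MEK5/CA in each pair, from 1.60-fold for MAP2K5 to 21.4-fold for THBD.

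Of the 21 tested genes linked to a flow-protected endothelium 14 rose, 3 fell and 4 did not pass, or 15 and 5 adjusted over the list alone. Besides IGFBP5, THBD, KLF2 and KLF4, the increases included PTGDS, a prostaglandin D synthase (log2 2.99 ± 0.15), TEK, the angiopoietin receptor TIE2 (1.88 ± 0.13), and NOS3, the endothelial nitric oxide synthase, whose signal went from 917 ± 232 to 1762 ± 367 (log2 0.94 ± 0.15, adjusted p = 8.00e-04). ASS1, which supplies arginine to nitric oxide synthase, and the water channel AQP1, both named after their values were seen, rose by 2.67 ± 0.20 and 2.58 ± 0.32. Other probe sets gave 1.80 for PTGDS and, below the filter, 1.29 for AQP1. The 3 decreases were ADM (-1.04), TFPI (-0.38) and CYP1A1 (-0.45), the last 2 also named after their values were seen. ADM encodes the vasodilator peptide adrenomedullin, TFPI an inhibitor of the tissue factor pathway and CYP1A1 a monooxygenase. The mean log2 fold change of the list was 1.48 (camera adjusted p = 5.44e-07), and the list mean was above 0 in 8 of 8 pairs. With an estimated correlation the adjusted p was 0.0749. With the beta-actin ratio as a covariate NOS3, TFPI and CYP1A1 lost their calls (NOS3 log2 0.73, adjusted p = 0.0863, TFPI -0.14, CYP1A1 -0.04), and TFPI and CYP1A1 also lost them with arrays centred on the hybridization controls. CYP1A1 was not called without the pairing, with 5 pairs, without the trend or without replicate 1, 2, 3, 4 or 8, and without any 1 replicate its log2 fold change lay between -0.54 and -0.32.

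Genes of coagulation and fibrinolysis went both ways. Of 15 tested, 5 rose and 5 fell, or 5 and 7 adjusted over the list alone. THBD, a cofactor in the activation of the anticoagulant protein C, was 21.4-fold higher, and PLAT, which encodes tissue plasminogen activator, rose by 1.66 ± 0.12. The increases counted here also include MMRN2 (1.73 ± 0.15), a gene that is on the pan-endothelial list as well. F2R, the thrombin receptor, fell by 0.59 ± 0.07. The list mean was 0.37 and its median -0.13, and the list did not stand apart (camera direction up, adjusted p = 0.784). The vasoactive list had 4 increases and 6 decreases among 13 genes, with the same counts adjusted over the list alone (adjusted p = 0.597, mean -0.09, or 0.20 with arrays centred on the hybridization controls). NPR1, a natriuretic peptide receptor, rose by 1.66 ± 0.18 and ECE1, the endothelin-converting enzyme, by 0.72 ± 0.10, whereas EDNRB, the type B endothelin receptor, fell by 0.75 ± 0.10. F2R lost its call with arrays centred on the hybridization controls (log2 -0.30, adjusted p = 0.0792) and without probe sets ending in _x_at or _s_at.

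The series also names responses to TNF, an inflammatory cytokine, although the labels mention no TNF treatment of these cultures. Of the leukocyte adhesion molecules that TNF induces, ICAM1 was 2.03-fold higher in MEK5/CA, at 1313 ± 1109 against 670 ± 590 (SD, n = 8; log2 1.02 ± 0.15, adjusted p = 5.09e-04, higher in 8 of 8 pairs). SELE had a signal of 201 ± 340 in MEK5/CA and 467 ± 599 in LacZ, and VCAM1 48.6 ± 16.4 and 89.4 ± 93.9, both below the filter. In the test without that filter SELE was lower (log2 -1.06 ± 0.29, adjusted p = 0.0210) and VCAM1 did not pass (-0.27 ± 0.37, adjusted p = 0.649). The chemokine gene CCL20 rose from 178 ± 231 to 1648 ± 1832. Its log2 fold change of 3.63 ± 0.47, with 1.16 to 6.16 in single pairs and 2.49 with the beta-actin ratio as a covariate, is not exact, because the CCL20 signal of 4 LacZ arrays was 8.14 to 29.8, close to background. The transcription factor gene IRF1 rose by 0.52 ± 0.08 and NFKBIA, which encodes the NF-kB inhibitor I-kappa-B alpha, by 0.38 ± 0.07. Among 18 tested genes of the list, 7 rose, 1 fell and 10 did not pass, or 9 and 2 adjusted over the list alone. The decrease was that of LTB (-1.06 ± 0.21), named after its values were seen, as were CXCL8 (0.72 ± 0.26, adjusted p = 0.0653) and CCL2 (-0.11 ± 0.26, adjusted p = 0.783), which did not pass, although CXCL8 did without replicate 8 (0.93, adjusted p = 0.0166) and with arrays centred on the hybridization controls. The list stood above the other genes (mean 0.42, camera adjusted p = 0.00925), but not with an estimated correlation (adjusted p = 0.352), without the pairing (adjusted p = 0.0594), without the filter (adjusted p = 0.141), without probe sets ending in _x_at or _s_at (adjusted p = 0.0609) or with the beta-actin ratio as a covariate (adjusted p = 0.0549). ICAM1 was not called without the pairing (adjusted p = 0.0889) or with that covariate (log2 0.72, adjusted p = 0.0732), and NFKBIA and LTB were not called without the pairing, nor was LTB with the covariate.

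Of 17 tested components of TNF receptor signalling 5 rose and 1 fell, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.105). CFLAR, an inhibitor of caspase 8 activation, was 1.89-fold higher (log2 0.92 ± 0.12), TNFRSF1A, the main TNF receptor, rose by 0.48 ± 0.08 and the adaptor FADD by 0.45 ± 0.07, while TNFRSF21 fell by 0.60 ± 0.14. Without probe sets ending in _x_at or _s_at CFLAR was at 0.34, still called. With the beta-actin ratio as a covariate TNFRSF1A (adjusted p = 0.100) and TNFRSF21 were not called, and TNFRSF21 also lost its call without the pairing and with arrays centred on the hybridization controls.

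Genes of angiogenesis had 8 increases and 4 decreases among 22 tested, or 10 and 5 adjusted over the list alone. Besides ADAMTS1 and TEK, NID2, a basement membrane protein, rose by 1.81 ± 0.15 and FLT1, a VEGF receptor, by 1.69 ± 0.14, although another FLT1 probe set, below the filter, was not called (0.30). The list did not pass (adjusted p = 0.0747), although it did with quantile normalization (adjusted p = 0.0482), with arrays centred on the hybridization controls (0.0300) and without replicate 4 (0.0409) or 8 (0.0402). In the Notch and arterial list 1 gene rose, 5 fell and 10 did not pass, or 2 and 8 adjusted over the list alone. The Notch ligand DLL4 fell by 0.98 ± 0.09, the Notch target HEY1 by 1.08 ± 0.17, the ephrin EFNB2 by 0.75 ± 0.17 and the transcription factor SOX17 by 0.74 ± 0.15. The increase was that of SOX7 (0.38 ± 0.10), named after its values were seen. The list mean was -0.27 (adjusted p = 0.0893), and 0.01 with arrays centred on the hybridization controls, where the list stood below the other genes (adjusted p = 0.00385). With the beta-actin ratio as a covariate HEY1 (adjusted p = 0.104), EFNB2, SOX17 and SOX7 were not called, and SOX7 was not called without the pairing or with the 5 pairs.

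Genes induced by interferon rose as a group. Of 11 tested, 7 rose, none fell and 4 did not pass, or 8 and 0 adjusted over the list alone. OAS2 rose by 2.01 ± 0.19 and OAS1 by 1.75 ± 0.13, both sensors of double-stranded RNA, IFI35 rose by 0.81 ± 0.09 and IFIT3 by 0.50 ± 0.10. ISG15 (0.12 ± 0.08, adjusted p = 0.314) and IFIT2 (0.11 ± 0.18, adjusted p = 0.700), named after their values were seen, did not pass, but ISG15 did with arrays centred on the hybridization controls (0.40, adjusted p = 0.0223). Another OAS2 probe set, below the filter, gave 0.80. The mean of the list was 0.70 (camera adjusted p = 3.94e-05), and it was the only list that also passed with an estimated correlation (adjusted p = 0.0374). The list mean lay between 0.54 and 0.94 in the 8 pairs.

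**Figure D2:**
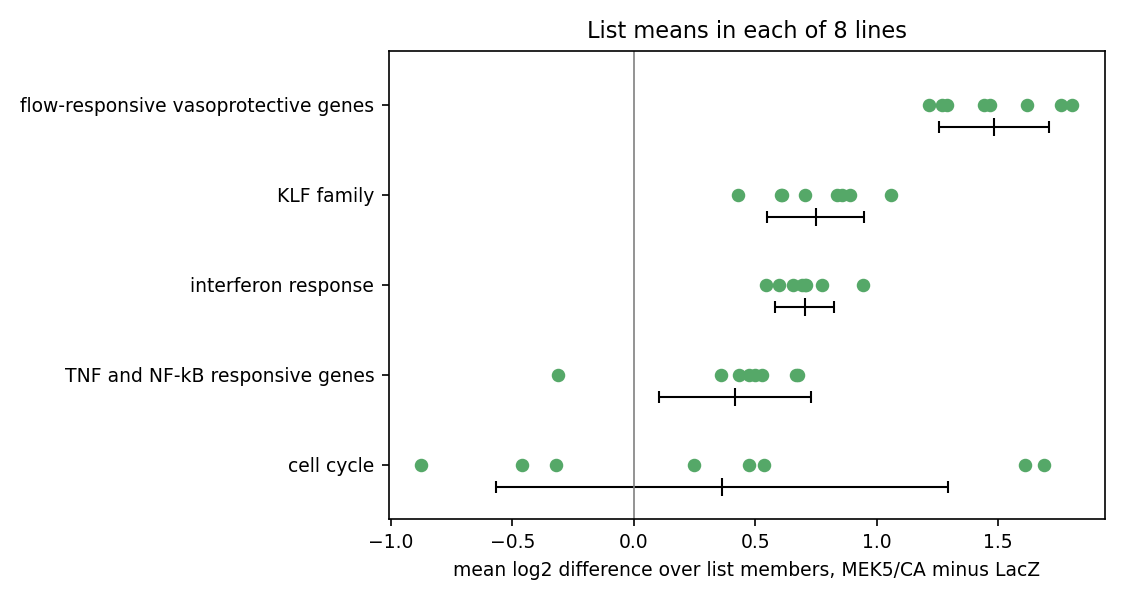
Mean log2 difference between the MEK5/CA and the LacZ array over the members of 5 gene lists, with a green point for each of the 8 pairs and the mean and SD in black. The means of the flow list (1.21 to 1.81), the Krüppel-like factors (0.43 to 1.06) and the interferon list (0.54 to 0.94) were above 0 in each pair, whereas those of the cell cycle list ran from -0.87 to 1.69.

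Of 15 tested genes of the unfolded protein response and of the ATF4 pathway, 6 fell, 1 rose and 8 did not pass, or 8 fell and 1 rose adjusted over the list alone. HERPUD1 fell by 0.41 ± 0.06, the chaperone HSP90B1 by 0.41 ± 0.09 and ATF4 itself by 0.33 ± 0.06, whereas DDIT4, a stress-induced inhibitor of mTOR signalling, rose by 1.12 ± 0.20. The list mean was -0.21 (camera adjusted p = 0.0118), with an adjusted p of 0.320 with an estimated correlation and 0.0504 without the pairing, and its mean was 0.07 with arrays centred on the hybridization controls. HERPUD1, HSP90B1 and ATF4 were not called with that centring or with the beta-actin ratio as a covariate, and HERPUD1 and HSP90B1 were not called without the pairing.

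In the TGF-beta and matrix list 4 genes rose and 10 fell among 27, or 5 and 11 adjusted over the list alone. LTBP1, which binds latent TGF-beta, fell by 1.27 ± 0.16, fibronectin (FN1) by 0.76 ± 0.11 and SPARC by 0.45 ± 0.06, while fibrillin 1 (FBN1) rose by 0.74 ± 0.09. Without probe sets ending in _x_at or _s_at FBN1 was at 0.45, still called. The list as a whole did not pass (mean -0.17, adjusted p = 0.0942), and with arrays centred on the hybridization controls its mean was 0.12 and it stood below the other genes (adjusted p = 0.0146). FN1 was not called without the pairing or with the beta-actin ratio as a covariate, nor SPARC with that centring (adjusted p = 0.205) or without probe sets ending in _x_at or _s_at.

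The mean of the cell cycle list was 0.36, and camera placed it above the other genes with the preset correlation (adjusted p = 0.0170) but not with an estimated one of 0.869 (adjusted p = 0.659). In it 1 gene rose, 1 fell and 28 of 30 did not pass, and 0 passed in either direction when adjusted over the list alone. MCM6, a subunit of the replicative helicase, rose by 0.43 ± 0.14 and the cell cycle inhibitor CDKN1A fell by 0.27 ± 0.08, a value of 0.01 with arrays centred on the hybridization controls. PCNA (0.44 ± 0.22) and MCM3 (0.27 ± 0.12) did not pass, but both did with that centring (0.73 and 0.55). Without any 1 replicate PCNA lay between 0.28 and 0.59 and was not called. The list mean was above 0 in 5 of 8 pairs and ran from -0.87 to 1.69 (exact sign-flip p = 0.312). The adjusted p was 0.0504 without the pairing and 0.918 with the beta-actin ratio as a covariate, and neither MCM6 nor CDKN1A was called in these 2 settings (0.20 and -0.12 with the covariate). The list was not called without replicate 2 (mean 0.17, adjusted p = 0.197) or 8 (0.18, adjusted p = 0.131) or with array quality weights (adjusted p = 0.0604). MCM6 was not called with 5 pairs, without the trend or without replicate 1, 2, 4, 7 or 8 (log2 0.32 to 0.45) and CDKN1A not without replicate 1, 2, 3, 4, 6 or 8 (-0.27 to -0.24), while MCM3 passed without replicate 5 (0.35, adjusted p = 0.0484).

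Markers of cell identity were examined to see whether the composition of the cultures differed. Of 19 pan-endothelial genes 7 rose and none fell, or 7 and 2 adjusted over the list alone (mean 0.35, camera adjusted p = 0.010, and 0.301 with an estimated correlation). TEK, MMRN2 and the adhesion molecule genes ESAM (1.58 ± 0.11) and ICAM2 (0.46 ± 0.08) rose. The most commonly used markers, named after their values were seen, did not pass. The log2 fold change was 0.06 ± 0.07 for PECAM1, 0.06 ± 0.07 for CDH5 and -0.37 ± 0.14 for VWF (adjusted p = 0.0703). PECAM1 was called higher with quantile normalization (0.24, adjusted p = 0.00353), and both PECAM1 and CDH5 with arrays centred on the hybridization controls. VWF was called lower without replicate 6 (-0.44) or 7 (-0.46) and with the mean of its probe sets (-0.49). Lymphatic endothelial markers were mixed, with 3 increases and 2 decreases among 9 genes, or 4 and 2 adjusted over the list alone (adjusted p = 0.176). ITGA9 rose by 1.47 ± 0.12, TFF3 by 0.85 ± 0.12 and podoplanin (PDPN) by 0.60 ± 0.09, while PROX1, the transcription factor that specifies lymphatic identity, fell by 0.42 ± 0.10. The list passed without the filter (adjusted p = 0.0452) or with the beta-actin ratio as a covariate (adjusted p = 0.0156), where PDPN (0.37) and PROX1 (-0.15) were not called, and PROX1 was not called without the pairing or with arrays centred on the hybridization controls (-0.13) either.

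Of 6 tested fibroblast and mural cell markers 2 rose and 1 fell, with the same counts adjusted over the list alone (adjusted p = 0.307). TAGLN rose by 1.24 ± 0.21 and ACTA2 by 0.30 ± 0.10, both contractile proteins, and the matrix protein POSTN fell by 0.82 ± 0.18. COL1A1, the main collagen of fibroblasts, had a signal of 7448 ± 10419 in LacZ and 7600 ± 8190 in MEK5/CA (SD, n = 8) and did not pass (0.52 ± 0.31, adjusted p = 0.249). The value for COL1A1 was 0.13 without replicate 3, where the pair differed by 3.19, and it passed with arrays centred on the hybridization controls (0.80). The COL1A1 signals of replicates 7 and 8 were 19870 to 24792 in both groups, and the highest of the other arrays was 6784. Below the filter RGS5, a gene of pericytes named after its values were seen, rose in the test without the filter (155 ± 40.1 to 337 ± 180, 0.93 ± 0.18, adjusted p = 0.00339). Of 4 keratinocyte and epithelial markers, PERP (0.24 ± 0.05) and SFN (0.39 ± 0.12) rose and KRT10 (-0.58 ± 0.09) and DSP (-0.39 ± 0.11) fell, again with the same counts over the list alone (adjusted p = 0.864). None of the leukocyte markers passed the filter, and 6 had a probe set with a single symbol in the table. PTPRC, the pan-leukocyte marker CD45, had a signal of 23.6 ± 13.0 in LacZ and 22.3 ± 13.3 in MEK5/CA. In the test without the filter CD14, named after its values were seen, rose (1.74 ± 0.30, adjusted p = 0.00132), and the other 5 of the 6 did not pass. Without the pairing ACTA2, POSTN, PERP, SFN and DSP were not called, and with the beta-actin ratio as a covariate these and TAGLN were not called (TAGLN 0.79, POSTN -0.50, SFN 0.15). Another TAGLN probe set, below the filter, was not called (0.06). Centring on the hybridization controls ended the calls of KRT10 and DSP, and with 5 pairs ACTA2, PERP and DSP were not called. ACTA2 was not called without the filter or with arrays scaled to a common median, and was called without replicate 5 but not without any other replicate (log2 0.22 to 0.32), DSP was not called without replicate 1, 6 or 8 (-0.36 to -0.35), and SFN was not called without replicate 1, 2, 3, 4 or 6 (0.29 to 0.40).

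**Figure D3:**
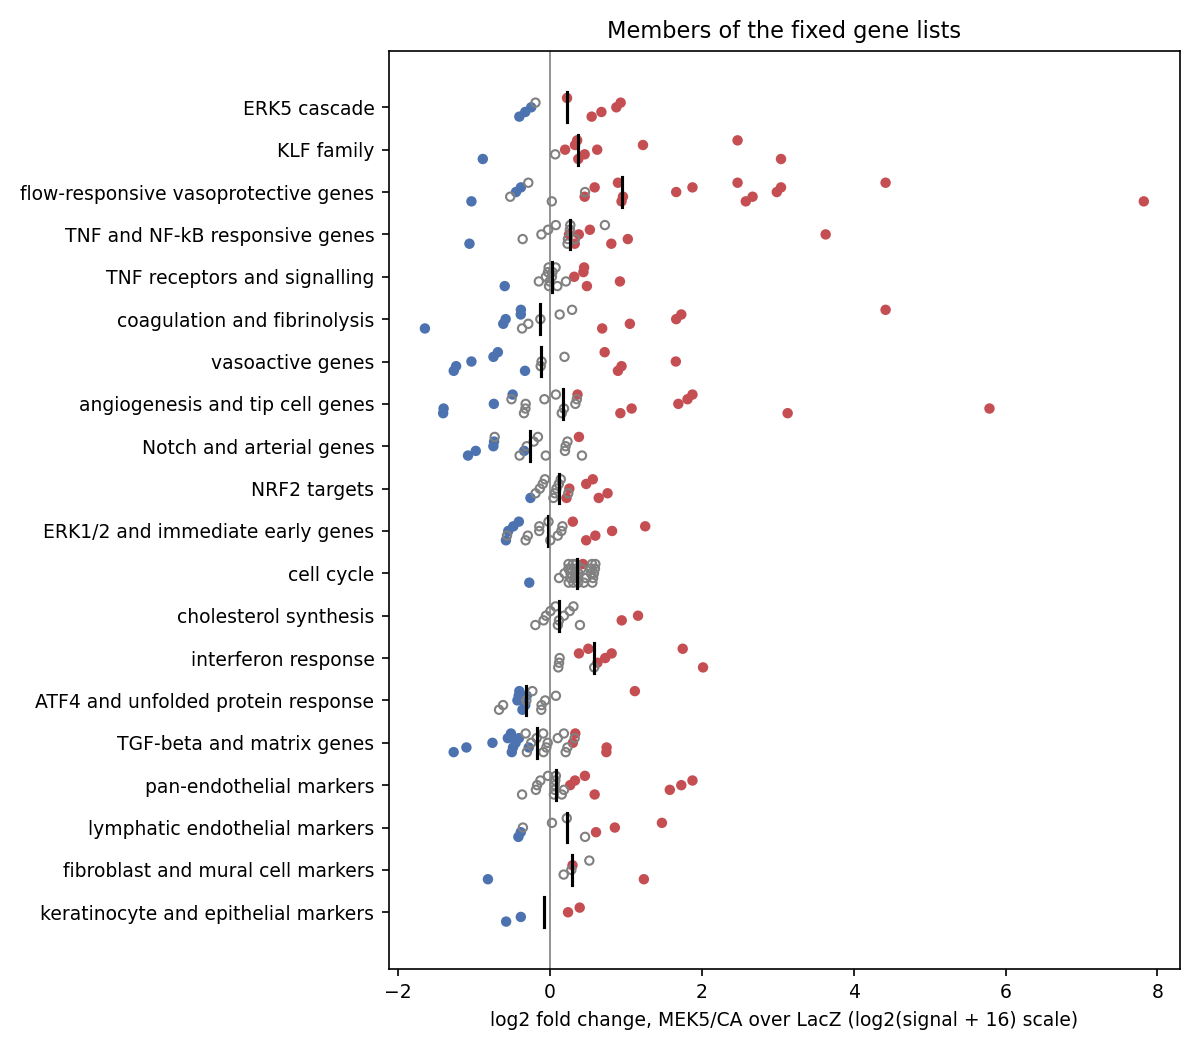
Log2 fold change, MEK5/CA over LacZ, of each tested member of 20 gene lists on the log2(signal + 16) scale. Filled points passed at an adjusted p below 0.05 (red higher, blue lower), open points did not, and the black bar is the median of the list, which is 0.94 for the flow list and 0.58 for the interferon list.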

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

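In each group of 8 arrays the array farthest from the others was looked for in every named gene and array measure. Across 260 such groups, 17 had an array whose distance to the nearest other array exceeded the limit for its share of the range of the group, against about 13 by chance, since chance alone gives about 1 in 20. Values below are that share, and the log2 signals of the array and of its nearest neighbour are given for the greatest.

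Replicate 4 stood high in several inflammatory genes. In MEK5/CA replicate 4, ICAM1 was at 11.98 against 10.10 for the next array (share 0.767), NFKBIA stood apart with 0.680, LTB with 0.673, CCL2 with 0.588 and TNFRSF1A with 0.550. NFKBIA also stood high in LacZ replicate 4 (0.580), as did the log2 3' to 5' ratio of GAPDH in that array (0.538). LTB and CCL2 were named only after their values were seen. The ICAM1 call held without replicate 4, where ICAM1 was among the 113 of 118 named genes with the same call and direction.

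In LacZ, S100P was low in replicate 3 (4.83 against 6.62, share 0.729), RNASE1 low in replicate 2 (0.694), DNASE1L3 low in replicate 6 (0.562) and KRT10 high in replicate 3 (0.544). In MEK5/CA, TFPI2 was low in replicate 3 (8.89 against 12.08, share 0.589), FREM3 low in replicate 3 (0.552), PTGDS low in replicate 1 (0.577), FADD high in replicate 1 (0.653), IFIT3 low in replicate 1 (0.530) and SRXN1 high in replicate 2 (0.556).

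Probe sets without a gene symbol took no part in the gene comparisons. Of 1214 past the filter, 261 were called in the same kind of fit, 96 higher and 165 lower, with 16 at least 2-fold higher and 3 at least 2-fold lower. Their log2 fold changes ran from -1.42 to 2.16.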

How the results depend on the processing

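Of the alternatives, 2 were chosen after seeing the data, the beta-actin ratio as a covariate and the centring on hybridization controls. KLF4 was called higher in all 21 alternatives that could test it (log2 2.89 to 3.36) and KLF2 in 21 (2.24 to 2.87), while MAP2K5 was called higher in 21 of 22 and had a value of -0.039 without probe sets ending in _x_at or _s_at, an alternative that leaves only the probe set without a change. The flow, interferon and pan-endothelial lists were called in all 22 with the preset correlation between genes, and with an estimated one in the original fit the interferon list alone passed (adjusted p = 0.0374, flow list 0.0749, pan-endothelial list 0.301).

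Without the replicate block 749 genes were higher and 662 lower, and 1409 of these 1411 were among the calls of the paired fit. The TNF list lost its call (mean 0.42, adjusted p = 0.0594), as did the cell cycle and ATF4 lists and 24 of 118 named genes, and no other list changed its call. With the beta-actin covariate 474 genes were higher and 213 lower, 652 of them among the original calls. The median standard error of the called genes under 2-fold rose from 0.0837 to 0.129 under the covariate, and their median absolute log2 fold change went from 0.375 to 0.342. The TNF list had a mean of 0.27 and 39 named genes lost their calls. With arrays centred on the hybridization controls 3359 genes were higher and 187 lower, 333 and 25 of them at least 2-fold, since this moved the median of all genes by 0.28. In that setting CDKN1A was at 0.0103 and GCLC at 0.0257, both turned in sign and not called, 13 other named genes lost their calls and 9 gained one. Averaging to 5 pairs gave 803 lower genes. At 2-fold or more 317 genes were higher and 94 lower without the filter, 114 were higher with the filter at the 60th percentile (7163 genes tested) and 119 without probe sets ending in _x_at or _s_at (6840 tested). Without those probe sets the Krüppel-like factor list, which then lacks KLF2 and KLF4, had a mean of 0.0935, and the TNF list a mean of 0.71 with adjusted p = 0.0609. Without the filter the TNF list had a mean of 0.14, since its members below the filter then counted. It held 29 genes in place of 18. Of the added members F3 (-1.33) and SELE (-1.06) were called lower and IL6 (0.79) higher, and the others did not pass. The cause of the other changes in the TNF list was not tested.

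Leaving out each pair in turn gave 1881 to 2403 called genes. Pseudocounts, quantile normalization, median scaling, array weights and eBayes without trend changed the calls of at most 2 named genes each. Signal close to background limits genes such as VCAM1, whose signal of 48.6 lies well under the filter limit of 292.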

Other observations

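The tests on RNA integrity and on the resemblance of lines, and the swaps of lines together, were chosen after the results they address were seen. Genes outside the naming rule, given in this and the following paragraph, were chosen after their values were seen. ANGPT2, the angiopoietin that can antagonise TIE2, fell by 1.41 ± 0.16 on the log2 scale (32081 ± 7195 to 12717 ± 5087, SD, n = 8, limma adjusted p = 8.35e-05), while its receptor gene TEK rose. ESM1, a gene of endothelial tip cells, fell by 1.40 ± 0.26 (a value of -2.08 with the beta-actin ratio as a covariate), whereas APLN, which encodes the peptide apelin, rose by 3.13 ± 0.40, with 0.63 to 5.12 in single pairs of which 1 had a LacZ signal close to background. GUCY1A1 and GUCY1B1, the subunits of the nitric oxide receptor guanylate cyclase, fell by 1.24 ± 0.26 and 1.27 ± 0.24 beside the increase of NOS3. The calls of both GUCY1A1 and GUCY1B1 were lost with that covariate (-1.18 and -1.43).

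Several genes below the signal filter differed in the test without the filter. F3, tissue factor, had a signal of 450 ± 157 in LacZ and 169 ± 54.2 in MEK5/CA (log2 -1.33 ± 0.17, adjusted p = 1.62e-04), and PTGS2, cyclooxygenase 2, 427 ± 229 and 171 ± 57.8 (-1.15 ± 0.25). PLAU, urokinase, was higher at 499.7 ± 279 against 98.1 ± 50.1 (2.13 ± 0.31), as were IFI27 (2.09 ± 0.30), NHERF2 (1.85 ± 0.18) and CD14, an endotoxin co-receptor known from monocytes (474 ± 236 against 155 ± 134, 1.74 ± 0.30). Of the other interferon list members below the filter, IFI44 rose (1.02 ± 0.19), whereas IFIT1, MX1, RSAD2 and XAF1 did not pass.

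Of 17 tested NRF2 targets, antioxidant genes, 6 rose and 1 fell, or 7 and 1 adjusted over the list alone (mean 0.17, camera adjusted p = 0.0893). NQO1 rose by 0.76 ± 0.17, SLC7A11 by 0.56 ± 0.12, SRXN1 by 0.48 ± 0.08 and NFE2L2, which encodes NRF2, by 0.22 ± 0.04, and GCLC, named after its values were seen, fell by 0.26 ± 0.08. None of these 5 was called with the beta-actin covariate (SLC7A11 at 0.22), and of them SRXN1 alone was called without the pairing. The list passed with quantile normalization (adjusted p = 0.0327), without replicate 3 (0.0340), without probe sets ending in _x_at or _s_at (0.0450) and with arrays centred on the hybridization controls, where GCLC was at 0.03. GCLC was called without replicate 4 or 5 but not without any other replicate (log2 -0.27 to -0.20), nor with 5 pairs or without probe sets ending in _x_at or _s_at (-0.17). In cholesterol synthesis 2 of 13 genes rose and 0 fell, also adjusted over the list alone (adjusted p = 0.0893). They were SQLE (1.16 ± 0.19) and STARD4 (0.94 ± 0.10), while MSMO1 (0.39 ± 0.16) and NSDHL (0.31 ± 0.13) did not pass. The list passed without replicate 3 (adjusted p = 0.0202), where MSMO1 did too (0.50), and with arrays centred on the hybridization controls (0.0373), where MSMO1 and NSDHL did too, and the call of SQLE was lost with the beta-actin covariate (0.73). ERK1/2 and immediate early genes had 5 increases and 4 decreases among 19, or 5 and 6 adjusted over the list alone (mean 0.02, median -0.02, adjusted p = 0.864). DUSP4, a phosphatase of ERK kinases, rose by 1.25 ± 0.17, JUN by 0.82 ± 0.14 and IER2 by 0.47 ± 0.06, and IER3 fell by 0.58 ± 0.12. JUN and IER3 were not called with the covariate, JUN not without probe sets ending in _x_at or _s_at, and IER3 neither without the pairing nor with arrays centred on the hybridization controls.

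Chance was weighed by swapping the labels within pairs in 100 of the 128 possible ways, the real one included, so that every split parted all 8 pairs. The real split alone gave as many higher genes (1184 against at most 446 in another), as many lower genes (1253 against 446) and as many genes at least 2-fold higher (186 against 106), 1 of 100 splits each, and 2 of 100 gave as many at least 2-fold lower (56 against 106). On the scale of -log10 of the camera p, 1 of 100 splits reached the value of the Krüppel-like factors (5.18, highest other 4.56), of the flow list (7.57 and 5.79) and of the interferon list (5.41 and 4.89). If the 8 pairs are independent, these shares of 1 or 2 in 100, not adjusted for the number of results, argue against chance for these 7 results. Lines whose labels share a number resembled each other, as given below, so their independence is in doubt. Chance stays open for the pan-endothelial list (7 of 100 splits, 2.60 against 3.60), the ATF4 list (18 of 100, 2.45 against 4.30), the TNF list (25 of 100, 2.73 against 7.83) and the cell cycle list (60 of 100, 2.23 against 29.1). These splits compare a list with the other genes. Whether the list mean differed from 0 over the 8 pairs is a separate question, and there the exact sign-flip p was 0.00781, the smallest that 8 pairs can give, for the pan-endothelial list (above 0 in 8 of 8) and the ATF4 list (above 0 in 0 of 8), and 0.0156 for the TNF list (7 of 8). Adjusted over the 20 lists these were 0.0130, 0.0130 and 0.0240. The smallest p was reached by 12 of the 20 lists, of which 7 did not pass with camera, so it does not set these lists apart. If the pairs are independent, these values argue against chance for these 3 means as differences from 0, though not for their place among the other genes. With an estimated correlation between genes, 0.172 for the Krüppel-like factors and 0.0846 for the flow list, neither of these lists passed (adjusted p = 0.160 and 0.0749). These losses cannot be put down to correlation alone. The camera p of the interferon list also rose, from 3.94e-06 to 0.00187, at an estimate of -0.00385. The estimated correlation was 0.869 for the cell cycle list and 0.209 for the TNF list, against a preset 0.010. When lines whose labels share a number were swapped together, 5 units gave 16 splits, too few for a share under 0.05. In them the real counts of 1184 higher and 1253 lower genes stood against 0 called by limma in any other (3606 genes at an unadjusted p under 0.05 in the real split, at most 2282 in another). The list values stood against at most 3.84 (Krüppel-like factors), 5.44 (flow list) and 4.03 (interferon list).

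The lower 3' to 5' ratio of beta-actin in MEK5/CA raised the question whether RNA integrity could stand behind the called genes. With the ratio as a covariate the 242 called genes with at least a 2-fold change kept a median of 0.962 of their log2 fold change (interquartile range 0.835 to 1.08), all 242 kept their direction and 191 were still called. For the 2195 smaller changes the median was 0.896 (0.677 to 1.11), 2193 kept their direction and 461 were still called. Their median absolute log2 fold change went from 0.375 to 0.342 while the median standard error rose from 0.0837 to 0.129, so the calls ended mainly with the larger error. These values argue against RNA integrity, as far as this 1 control ratio measures it, as the whole cause of either set. A contribution to the smaller changes stays open, as does an effect of the transduction on the control transcripts themselves.

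The cell cycle list was above the other genes on average, yet its mean difference was 0.48, 1.69, -0.46, 0.53, -0.87, -0.32, 0.25 and 1.61 in the 8 lines. A scale factor common to an array moves all its genes about alike, so it cannot place the list above the other genes. Centring on the hybridization controls moved the other genes by a median of 0.285 and took the list mean from 0.36 to 0.65. A scaling that depends on signal level stays undecided. The list mean was at least 0.35 under quantile normalization and median scaling, but these moved the other genes by a median of only 0.00997 and 0.0114, too little to test it. The list means of the LacZ arrays had an SD of 0.92 and those of the MEK5/CA arrays of 0.56, so cultures of the same group differed by more than the groups did. A candidate explanation is that growth state differed between single cultures and not by transduction, in line with an exact two-sided sign-flip p of 0.312 over the 8 lines. An effect of MEK5/CA that differs between lines is not excluded by this test.

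Lines whose labels share a number, 3 couples among the 8, may not be independent. In signal levels, deviations from the group means correlated at 0.369 on average within couples and -0.20 between other lines (exact one-sided p = 0.00476). For the response to MEK5/CA, the deviations of the paired differences from their mean over the 8 pairs were used. The averages were 0.135 and -0.17 (exact one-sided p = 0.0333), from 0.284 and 0.293 in 2 couples and -0.17 in the remaining one, which was thus no closer than other lines. Taking off a mean pushes correlations between lines below 0. Without that step the paired differences correlated at 0.688 within couples and 0.572 between other lines. The levels, and the response in those 2 couples, are consistent with a shared isolate, culture time or array batch, which the test does not separate, and no biological explanation was tested. With each couple averaged to 1 pair, 854 genes were higher and 803 lower, 1638 of them among the calls from 8 pairs.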
